A study of Mus musculus with 6 samples.

How the data were processed

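Single-nucleus RNA sequencing was done on 2 libraries in each of 3 groups of mice. Per the labels, nuclei stained with DAPI were sorted from brain tissue and libraries were made with a droplet 3' chemistry. The authors deposited raw UMI counts per gene and nucleus barcode, made with Cell Ranger 6.0.1 and genome build GRCm39 according to the submitters' processing notes and the file headers. The deposited barcode and feature files hold names only, in the unit other, from the values. The barcodes were already restricted to called nuclei, and how nuclei were called beyond this is not given in the sources used here. No gene coordinates are printed, because the annotation at hand is of another build.

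Nuclei with at least 500 genes and at most 5% mitochondrial counts were kept, 64650 of 65412. Scrublet, run per library with an expected rate of 0.08, called 4320 doublets, which were removed. Counts were scaled to 10000 per nucleus and log-transformed, and 3000 variable genes, 40 principal components and 20 neighbours were used for Leiden clustering at resolution 1. This gave 45 clusters, of which 6 with over 50% called doublets were left out and 9 kept without a name. Clusters were named from marker genes of 21 classes. The naming thresholds, a z score of 1.5 and markers detected in 10% of nuclei, were set after the data were seen. The tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

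UMI counts were summed per library over the nuclei of a class with at least 20 nuclei in each library. Sums were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, robust quasi-likelihood F test, two-sided), over all 6 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in its class and comparison, and "rose" and "fell" are used of called genes. CPM are TMM-scaled. Of 27 gene lists, those with at least 5 tested members were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01. The correlation estimated per list and fry were run beside it. Shares of nuclei were compared by two-sided exact permutation tests of library values, with 95% Wilson intervals that cover counting error only. Groups, comparisons, tests, gene lists and the rule for naming genes were set before the data were examined. Some genes that this rule names are not reported here.

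Genes named were, in microglia and macrophages, the 8 called genes with the largest rise and the 8 with the largest fall whose libraries did not overlap between groups. In each other class they were the 3 largest of each by the same rule. Up to 3 called members of each called list, and a fixed set given whatever its result, were added. Predicted, mitochondrial, ribosomal and hemoglobin genes and markers of other classes were left out of the first parts. The edgeR test was tested on simulated data made from these sums. For microglia and macrophages it recovered 21, 11 and 29 of 100 genes changed 2-fold, and 78, 65 and 79 of those changed 4-fold, in wild-type marrow against control, knockout marrow against control and knockout against wild-type marrow. False calls numbered 6, 7 and 15. Over 15 such runs in 5 classes, 5.41% to 14.6% of calls were false, above the 5% set, in every run. Each run held 200 genes changed 2-fold or 4-fold, while the real comparisons in these classes called from 1 to 682 genes. These shares therefore do not carry over to comparisons with few calls, where a larger part of the calls may be false.

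Alternatives were edgeR RLE size factors, the DESeq2 1.42.0 Wald test, no filter on low counts and only the libraries of the 2 groups compared. Others were the replicate number as a block, each library left out, doublets kept, at least 1000 genes per nucleus and Leiden resolution 2. The share was also computed over non-neuronal nuclei. Single clusters taken alone were chosen after seeing the data. Endothelial cells had too few nuclei and were left out, and no alternative was run for them.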

Results

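Single-nucleus RNA sequencing was performed on brain tissue of female mice, aged 12 weeks, with the genotype label B6.Csf1r-eGFP x DBA2 F1. All mice had an allogeneic transplantation and were sampled at day 70. The 6 libraries form 3 groups of 2. The wild-type-marrow group received wild-type marrow and donor T cells, which cause graft-versus-host disease (GVHD), an attack of donor immune cells on the recipient's tissues. The knockout-marrow group received marrow lacking the interferon-gamma receptor together with wild-type donor T cells. The control group, with WT in its titles, received no donor T cells. Total UMI counts were 66837715 and 88230595 in the wild-type-marrow libraries, 100667147 and 88372971 in the knockout-marrow libraries and 53440673 and 96091782 in the control libraries. After filtering, 60226 of 65412 nuclei were kept, 8362 and 10825 in the wild-type-marrow libraries, 11979 and 10636 in the knockout-marrow libraries and 6806 and 11618 in the control libraries.

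Nuclei were grouped into classes by marker genes, and expression was compared between libraries within a class. The microglia and macrophage class joined cluster 21, led by Inpp5d, Ly86 and Dock8, and cluster 19, led by Cd74, Fyb and Apobec1. Before doublets were removed, 33.8% of cluster 19 and 0.574% of cluster 21 were called doublets. At the alternative Leiden resolution, 276 candidate nuclei of this class formed a separate cluster with 81.5% called doublets and a median of 8460 UMIs. Doublets that were not called may therefore remain in the class, and their share was not tested. Cluster 21 held the following numbers of nuclei: 116 and 265 in the wild-type-marrow libraries, 143 and 274 in the knockout-marrow libraries and 132 and 283 in the control libraries. Cluster 19 held 141 and 176 in the wild-type-marrow libraries, 82 and 66 in the knockout-marrow libraries and 18 and 27 in the control libraries. Clusters left without a name held 22.9% and 19.4% in the wild-type-marrow libraries, 31.1% and 19% in the knockout-marrow libraries and 22.8% and 20.4% in the control libraries. Each of these 9 clusters had excitatory neurons as its candidate class. Most were left unnamed because more of their leading genes were markers of another class. The largest, cluster 1, held 6256 nuclei before doublets were removed. The excitatory neurons counted and tested below may therefore be incomplete.

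The labels name the interferon-gamma receptor as knocked out in the marrow without saying which subunit, so both subunits were read first. Over all nuclei, the CPM (UMI counts scaled to library size) of Ifngr1 (ENSMUSG00000020009) were 6.24 and 6.56 in the wild-type-marrow libraries, 6.42 and 8.30 in the knockout-marrow libraries and 6.53 and 6.45 in the control libraries. Ifngr2 (ENSMUSG00000022965) had 15.7 and 18.4 in the wild-type-marrow libraries, 17.3 and 18.7 in the knockout-marrow libraries and 18.6 and 16.4 in the control libraries. In microglia and macrophages, Ifngr1 had 183 and 142 in the wild-type-marrow libraries, 191 and 289 in the knockout-marrow libraries and 193 and 193 in the control libraries. Neither subunit was lower with knockout marrow. The library chemistry reads the 3' end of transcripts, the labels give the knockout for the marrow and not for the recipient, and the deleted part is not given in the sources used here, so these values check neither the labels nor the knockout.

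Microglia and macrophages made up 3.57 ± 0.707% of nuclei with wild-type marrow and T cells (SD, n = 2), 2.54 ± 0.932% with knockout marrow and 2.44 ± 0.328% in controls. Single libraries, each with its 95% Wilson interval, had 3.07% (2.72 to 3.47) and 4.07% (3.72 to 4.46) in the wild-type-marrow libraries, 1.88% (1.65 to 2.14) and 3.20% (2.88 to 3.55) in the knockout-marrow libraries and 2.20% (1.88 to 2.58) and 2.67% (2.39 to 2.98) in the control libraries. The wild-type-marrow group exceeded controls by 1.14 percentage points and both of its libraries lay above both controls (two-sided exact permutation p = 0.333, n = 2 each). The knockout-marrow group exceeded controls by 0.101 points (exact permutation p = 1.0, n = 2 each) and differed from the wild-type-marrow group by -1.04 points (exact permutation p = 0.667, n = 2 each). With 2 libraries per group the smallest p these tests allow is 0.333. The knockout-marrow difference from controls was -0.106 points among nuclei with at least 1000 genes, -0.558 without knockout-marrow library 2, 0.761 without knockout-marrow library 1, -0.131 without control library 1 and 0.334 without control library 2. Leaving out knockout-marrow library 1 or 2 changed the difference between the marrow groups to -0.377 or -1.70 points, and without wild-type-marrow library 1 or 2 it was -1.54 or -0.536. The difference of the wild-type-marrow group from controls was 0.637 without wild-type-marrow library 2.

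**Figure D1:**
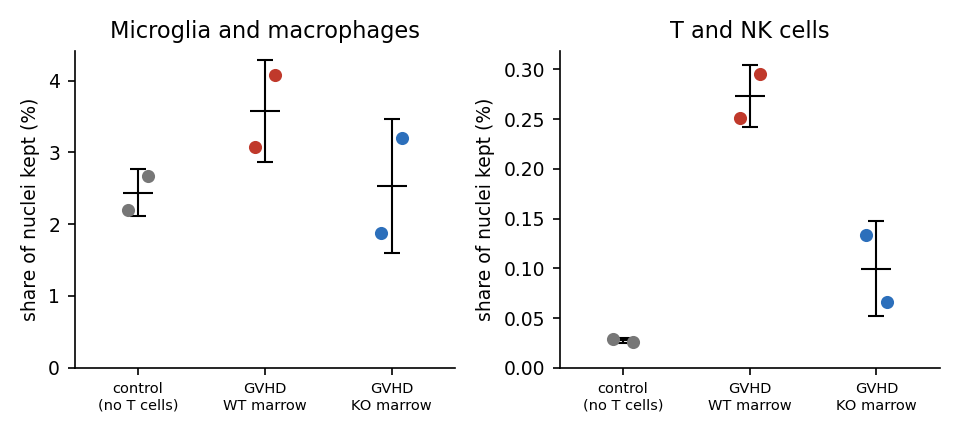
Percent of nuclei per library in the microglia and macrophage class and in the T and NK cell class, by group. Points are libraries, bars are group means and error bars are SD (n = 2). Both wild-type-marrow libraries lie above both control libraries in each class.

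The comparison of wild-type-marrow mice with controls asks what donor T cells and GVHD change in the brain. In microglia and macrophages, genes induced by interferon-gamma were higher. Ciita (ENSMUSG00000022504), the master regulator of MHC class II genes, had 109 ± 25.4 CPM with GVHD against 6.46 ± 0.977 in controls (SD, n = 2), a log2 fold change of 4.11 ± 0.43 (adjusted p 0.00102) by edgeR. Iigp1 and Gbp8, interferon-inducible GTPases that act against intracellular pathogens, rose by 5.54 ± 0.76 (adjusted p 0.0232) and 4.16 ± 0.55 (adjusted p 0.00235) on the log2 scale. H2-Eb1 (ENSMUSG00000060586), an MHC class II chain, rose by 2.9 ± 0.34 (adjusted p 0.00702) and Nlrc5 (ENSMUSG00000074151), a regulator of MHC class I genes, by 2.59 ± 0.38 (adjusted p 0.0163). Of 20 measured members of the interferon-gamma response list, 19 were higher and 6 rose, or 14 when adjusted over the list alone. Its median log2 fold change was 1.11 (camera, adjusted p 2.66e-18, or adjusted p 0.167 with an estimated correlation). The MHC class II list had 4 of 8 members risen, or 6 adjusted over the list alone (median 2.79, adjusted p 3.29e-13, or adjusted p 0.167 with an estimated correlation). The MHC class I list had 2 of 15 risen, or 12 adjusted over the list alone (median 1.19, adjusted p 1.18e-16, or adjusted p 0.167 with an estimated correlation).

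Markers of the origin of these cells were read next, over the class as a whole. On the marrow-derived macrophage list, 3 of 11 measured members rose, or 8 adjusted over the list alone (median 1.89, adjusted p 2.38e-12, or adjusted p 0.167 with an estimated correlation). Its members Ms4a7 (ENSMUSG00000024672), Ms4a6c (ENSMUSG00000079419) and Klra2 (ENSMUSG00000030187), a receptor of the Ly49 family, rose by 2.39 ± 0.41 (adjusted p 0.0347), 1.58 ± 0.32 (adjusted p 0.0378) and 3.43 ± 0.47 (adjusted p 0.0377) on the log2 scale. On the resident microglia list, 2 of 17 members fell, or 11 adjusted over the list alone (median -0.59, adjusted p 4.24e-13, or adjusted p 0.252 with an estimated correlation). These were Sparc (ENSMUSG00000018593), a matrix glycoprotein, at -0.98 ± 0.20 (adjusted p 0.0378), and Golm1 (ENSMUSG00000021556), a Golgi membrane protein, at -0.91 ± 0.20 (adjusted p 0.0468). Axl (ENSMUSG00000002602), a receptor kinase on the disease-associated list, rose by 2.21 ± 0.32 (adjusted p 0.00513). Ccnd3 (ENSMUSG00000034165), a cyclin of the G1 phase, had 305 ± 10.5 CPM against 741 ± 15.6 in controls, a log2 fold change of -1.28 ± 0.15 (adjusted p 0.00154). Plbd1 (ENSMUSG00000030214) had no count in the control libraries and was at least 14.1-fold higher, with 3 counts over the control group taken as its floor. The other named rises, of Xdh, Stard13, Slamf7, H2-Q6 and H2-DMb1, lay between 1.52 and 3.81. The other named falls, of Upk1b, Col27a1, P3h2, Ebf3, Pard3b and Mlph, lay between -1.54 and -1.13.

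Cluster 19 was a larger part of this class with wild-type marrow than in controls, so that changes of the class hold changes of its mix. In cluster 21 alone, chosen after seeing the data, 24 genes were called, the interferon-gamma response list had a median of 0.94, the MHC class II list 3.48 and the resident microglia list -0.10. Iigp1 and H2-Eb1 had 5.15 and 4.35 there. Sparc, Golm1 and Axl had -0.25, -0.26 and 1.52 and were not called. The marrow-derived macrophage list was not tested in cluster 21, nor was this comparison in cluster 19, which had fewer than 20 nuclei in a control library.

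Genes given whatever their result, which did not pass the test in this comparison, included Cd74 (ENSMUSG00000024610), the MHC class II chaperone, with 1045 ± 381 against 172 ± 95 CPM in controls (SD, n = 2), a log2 fold change of 2.67 ± 0.54 (adjusted p 0.276). H2-Ab1 (ENSMUSG00000073421) had 3.18 ± 0.56 (adjusted p 0.119), B2m (ENSMUSG00000060802) 0.85 ± 0.20 (adjusted p 0.0654) and Apoe (ENSMUSG00000002985) 1.89 ± 0.66 (adjusted p 0.572). The microglial receptors P2ry12 (ENSMUSG00000036353) and Csf1r (ENSMUSG00000024621) had -0.51 ± 0.15 (adjusted p 0.177) and -0.66 ± 0.15 (adjusted p 0.0629), and Tmem119 (ENSMUSG00000054675) had -0.74 ± 0.24 (adjusted p 0.240). Cd274 (ENSMUSG00000016496), the checkpoint ligand PD-L1, had 0.97 ± 0.42 (adjusted p 0.467) and Tgfb1 (ENSMUSG00000002603) had -0.56 ± 0.20 (adjusted p 0.337). Without control library 1, Cd74 and H2-Ab1 passed the test (log2 fold changes 3.33 and 4.12), and without control library 2 H2-Ab1 did (2.26). Csf1r passed it without knockout-marrow library 1 (-0.67) or 2 (-0.65).

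In this class 43 genes rose and 24 fell of 9255 tested, 841 had an unadjusted p under 0.05, and DESeq2 called 26, of which 18 were shared. The class held 150 to 441 nuclei and 291254 to 869916 UMIs per library. The mitochondrially encoded list, a sign of nuclear purity, was higher too (median 0.68, adjusted p 5.5e-05, or adjusted p 0.373 with an estimated correlation). Called genes in microglia and macrophages numbered 15 without wild-type-marrow library 1, 35 without wild-type-marrow library 2, 105 without knockout-marrow library 1, 102 without control library 1 and 29 without control library 2. Of the 24 named calls, 17 without wild-type-marrow library 1, 14 without wild-type-marrow library 2, 5 without control library 1 and 16 without control library 2 were lost, with an adjusted p of up to 0.623.

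**Figure D2:**
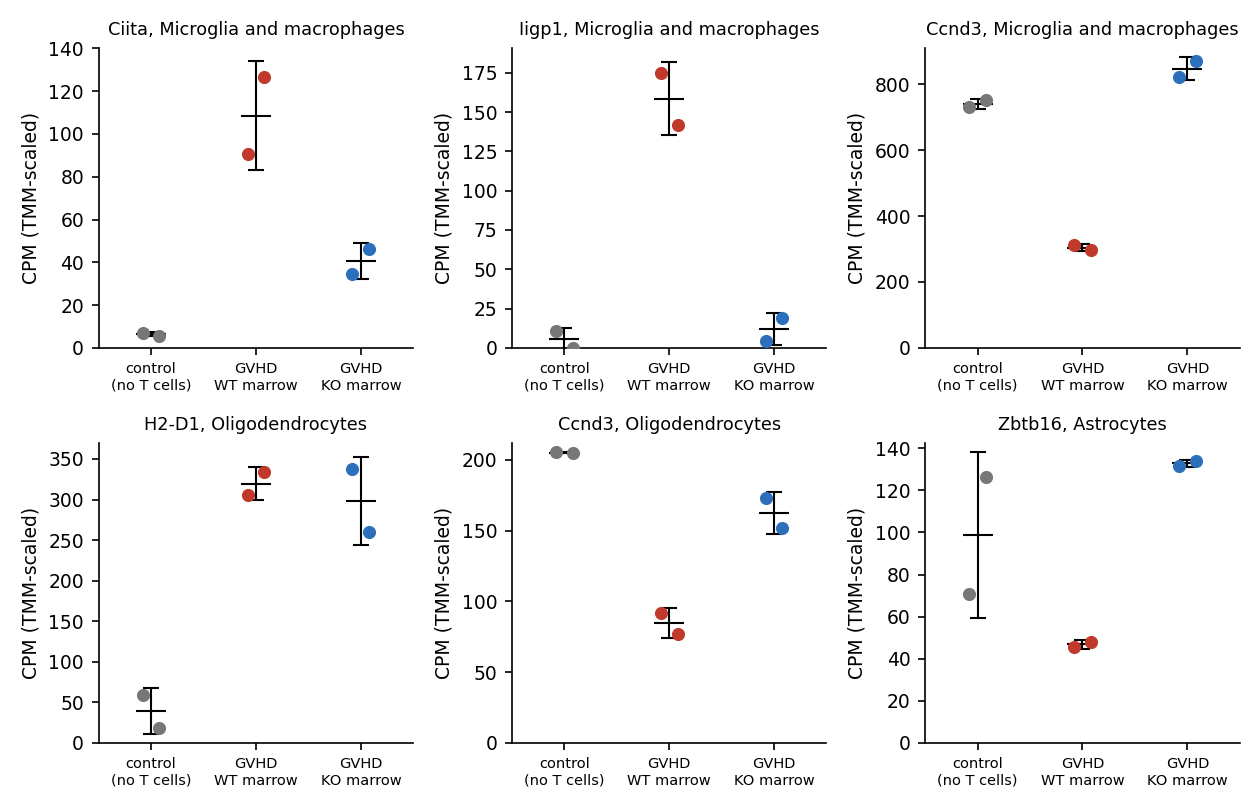
TMM-scaled CPM of Ciita, Iigp1 and Ccnd3 in microglia and macrophages, H2-D1 and Ccnd3 in oligodendrocytes and Zbtb16 in astrocytes, by group. Points are libraries, bars are group means and error bars are SD (n = 2). Ciita in microglia and macrophages had 90.6 and 126 CPM with wild-type marrow and T cells. It had 34.5 and 46.3 CPM with knockout marrow and 7.15 and 5.77 in controls. Between knockout marrow and controls Ciita was not called by edgeR (log2 fold change 2.69). Between knockout and wild-type marrow neither Ciita (-1.42, adjusted p 0.209) nor Iigp1 (-3.57, adjusted p 0.202) was called by edgeR. H2-D1 in oligodendrocytes was not called by edgeR against controls (adjusted p 0.345 with wild-type marrow and 0.486 with knockout marrow).

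Oligodendrocytes, the myelin-forming cells, also had higher interferon-induced genes in this comparison. Psmb8 (ENSMUSG00000024338), an immunoproteasome subunit, and Uba7 (ENSMUSG00000032596), the enzyme that activates the ubiquitin-like protein ISG15, had no count in either control library. They were at least 21.3-fold and 12.0-fold higher, with 3 counts over the control group as the floor. H2-T22 (ENSMUSG00000056116) and H2-Q7 (ENSMUSG00000060550), nonclassical MHC class I genes, had 22.6 ± 3.48 against 4.47 ± 1.42 CPM and 14.6 ± 1.94 against 0.571 ± 0.382 CPM (SD, n = 2), with log2 fold changes of 2.45 ± 0.28 (adjusted p 0.000254) and 4.91 ± 0.57 (adjusted p 0.000507) by edgeR. Ddx60 (ENSMUSG00000037921), Oasl2 (ENSMUSG00000029561) and Xaf1 (ENSMUSG00000040483), type I interferon targets, rose by 5.61 ± 0.47 (adjusted p 0.000254), 5.25 ± 0.64 (adjusted p 0.00120) and 1.23 ± 0.16 (adjusted p 0.000507). C4b (ENSMUSG00000073418), a complement gene of disease-associated oligodendrocytes, rose by 2.17 ± 0.29 (adjusted p 0.0440) and Stat3 (ENSMUSG00000004040) by 0.54 ± 0.12 (adjusted p 0.0309). Parp14, Gbp6 and H2-T23 rose by between 3.06 and 3.95. Among falls, Ccnd3 had -1.29 ± 0.11 (adjusted p 7.92e-06), Plin4 (ENSMUSG00000002831), a glucocorticoid target that coats lipid droplets, -2.36 ± 0.39 (adjusted p 0.00480), and Lmntd1 -1.88 ± 0.42 (adjusted p 0.0476). Serpina3n did not pass the filter on low counts in this class and was not tested. H2-Eb1 was called too, at least 12.3-fold higher, but microglial markers in oligodendrocytes stood at 0.667% and 0.544% of their microglia and macrophage level with wild-type marrow and in controls. At these shares, that class would bring 54.5% of the rise of H2-Eb1, which is not taken as a rise of oligodendrocytes.

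The interferon-gamma response list had 7 of 25 members risen in oligodendrocytes, or 22 adjusted over the list alone. Its median was 4.34, or 4.07 with the 4 members at 0 in a group set to their bound (adjusted p 1.13e-41, or adjusted p 0.169 with an estimated correlation). On the MHC class I list 7 of 15 rose, or 15 adjusted over the list alone (median 3.75, adjusted p 3.39e-39, or adjusted p 0.143 with an estimated correlation). On the type I interferon list 9 of 15 rose, or 13 adjusted over the list alone (median 2.57, adjusted p 1.21e-22, or adjusted p 0.143 with an estimated correlation). The myelin list was called lower with a median of -0.063 (adjusted p 0.0402, or adjusted p 0.387 with an estimated correlation) and none of its 12 members passed the edgeR test over all genes or adjusted over the list alone. Beside these lists, the mitochondrially encoded list had a median of 0.62 (adjusted p 7.98e-05, or adjusted p 0.387 with an estimated correlation). In all, 74 genes rose and 35 fell of 13175 tested, 1110 had an unadjusted p under 0.05, and DESeq2 called 69, 51 of them shared. The mix of clusters differed here too. Cluster 5 held 612 and 1098 nuclei in the wild-type-marrow libraries and 430 and 749 in the control libraries. Cluster 24 held 540 and 683 in the wild-type-marrow libraries and 611 and 1737 in the control libraries. Called genes in oligodendrocytes numbered 32 without wild-type-marrow library 2, 164 without control library 1 and 44 without control library 2. Of the 16 named calls, 2 without knockout-marrow library 1, 2 without knockout-marrow library 2, 2 without wild-type-marrow library 1, 8 without wild-type-marrow library 2, 1 without control library 1 and 9 without control library 2 were lost, with an adjusted p of up to 0.383.

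Astrocytes shared part of this pattern. Gbp6 (ENSMUSG00000104713) had 28.6 ± 0.636 against 4.28 ± 3.44 CPM in controls (SD, n = 2) and a log2 fold change of 3.09 ± 0.51 (adjusted p 0.00896) by edgeR. H2-D1 (ENSMUSG00000073411), a classical MHC class I gene, rose by 2.56 ± 0.38 (adjusted p 0.00767), Tap1 (ENSMUSG00000037321), the peptide transporter, by 2.59 ± 0.56 (adjusted p 0.0321) and Gbp7 (ENSMUSG00000040253) by 1.96 ± 0.31 (adjusted p 0.00407). Hmgcs1 (ENSMUSG00000093930), an enzyme of cholesterol synthesis, rose by 0.77 ± 0.14 (adjusted p 0.0115). Tmem117 (ENSMUSG00000063296), Slc24a4 (ENSMUSG00000041771) and Fzd10os (ENSMUSG00000072591) fell, with -1.90 ± 0.31 (adjusted p 0.00767), -1.72 ± 0.38 (adjusted p 0.0331) and -1.63 ± 0.37 (adjusted p 0.0430). Gfap (ENSMUSG00000020932), the filament protein of reactive astrocytes, had 0.43 ± 0.33 (adjusted p 0.793). The interferon-gamma response list had 4 of 20 members risen, or 12 adjusted over the list alone (median 2.11, adjusted p 9.56e-19, or adjusted p 0.244 with an estimated correlation). The MHC class I list had 2 of 10, or 8 adjusted over the list alone (median 1.99, adjusted p 6.7e-13, or adjusted p 0.244 with an estimated correlation). Beside these lists, the mitochondrially encoded list had a median of 0.31 (adjusted p 0.0348, or adjusted p 0.632 with an estimated correlation). In all, 32 genes rose and 38 fell of 11452 tested, 1021 had an unadjusted p under 0.05, and DESeq2 called 39. Cluster 36 held 44 and 37 in the wild-type-marrow libraries, 137 and 43 in the knockout-marrow libraries and 119 and 298 in the control libraries, and cluster 17 held the other astrocytes. Called genes in astrocytes numbered 22 without wild-type-marrow library 1, 5 without wild-type-marrow library 2, 222 without knockout-marrow library 1, 229 without knockout-marrow library 2, 128 without control library 1 and 21 without control library 2. Of the 8 named calls, 7 without wild-type-marrow library 1, 7 without wild-type-marrow library 2 and 7 without control library 2 were lost, with an adjusted p of up to 0.468.

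In excitatory neurons, compared in the same way, 133 genes rose and 120 fell of 18631 tested (2919 with an unadjusted p under 0.05, DESeq2 571). H2-D1 had 16.1 ± 0.380 against 8.85 ± 0.50 CPM (SD, n = 2) and a log2 fold change of 0.87 ± 0.12 (adjusted p 0.0128) by edgeR. Herc6 (ENSMUSG00000029798), an interferon-induced ligase, rose by 0.41 ± 0.085 (adjusted p 0.0430) and Hspa5 (ENSMUSG00000026864), the chaperone of the endoplasmic reticulum, fell, with -0.51 ± 0.087 (adjusted p 0.0224). Gapdh, chosen after its values were seen, had -0.42 ± 0.078 (adjusted p 0.0301). In cluster 0 alone, chosen after seeing the data, the value of Herc6 was -0.12. Gbp7 rose from a level under 1 CPM, by 3.34 ± 0.55 (adjusted p 0.0201). Cd74 and H2-Eb1 were called with 3.07 ± 0.45 (adjusted p 0.0138) and 4.74 ± 0.90 (adjusted p 0.0343), but Cd74 in these neurons stood at 0.167% with wild-type marrow and 0.122% in controls of its microglia and macrophage level, and H2-Eb1 at 0.175% with wild-type marrow and 0.0513% in controls. Microglial markers stood at 0.711% and 0.564%, higher than either gene, so these 2 calls are not taken as a rise of neurons. At these shares, microglia and macrophages would bring 23.6% of the rise of H2-D1, 25.8% of that of Gbp7 and 5.07% of that of Herc6. RNA from oligodendrocytes was not checked for these single genes. Hey2, Myof and Plekhd1 fell, with values from -1.66 to -1.23. The interferon-gamma response list had a median of 0.26, adjusted p 0.00364, 0.457 with an estimated correlation. The immediate early gene list, which marks neuronal activity, had a median of -0.32, adjusted p 0.00364, 0.618 with an estimated correlation. Regional clusters held unequal nuclei: cluster 27 had 64 and 0 in the wild-type-marrow libraries, 9 and 0 in the knockout-marrow libraries and 7 and 76 in the control libraries. Called genes in excitatory neurons numbered 95 without wild-type-marrow library 1, 39 without wild-type-marrow library 2, 783 without knockout-marrow library 1, 784 without knockout-marrow library 2, 5 without control library 1 and 29 without control library 2. Of the 9 named calls, 6 without wild-type-marrow library 1, 9 without wild-type-marrow library 2, 9 without control library 1 and 9 without control library 2 were lost, with an adjusted p of up to 0.275.

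In inhibitory neurons 414 genes rose and 268 fell of 16092 tested (2617 with an unadjusted p under 0.05, DESeq2 531). Ccdc192 (ENSMUSG00000058925), Otx1 (ENSMUSG00000005917) and Nmur2 (ENSMUSG00000037393), a neuromedin receptor, fell, with log2 fold changes of -3.50 ± 0.39 (adjusted p 0.000407), -2.84 ± 0.72 (adjusted p 0.0366) and -2.77 ± 0.67 (adjusted p 0.0365) by edgeR. Mafa and Runx2os2 rose by 2.67 ± 0.72 (adjusted p 0.0491) and 2.37 ± 0.61 (adjusted p 0.0407) from control levels under 1 CPM. Cd74 was called with 2.03 ± 0.55 (adjusted p 0.0497), but stood at 0.171% with wild-type marrow and 0.264% in controls of its microglia and macrophage level, below microglial markers at 0.745% and 0.766%, and is not taken as a rise of neurons. None of 22 gene lists was called by camera, and the smallest adjusted p with an estimated correlation was 0.838. Cluster 20, led by Rmst, 4930555F03Rik and Ebf1, held 133 and 61 in the wild-type-marrow libraries, 249 and 63 in the knockout-marrow libraries and 584 and 472 in the control libraries. In cluster 8 alone, the inhibitory cluster with the most nuclei in its smallest library, 77 genes were called, and in cluster 0 of the excitatory neurons 166. Malat1, a nuclear transcript chosen after its values were seen, had 0.32 ± 0.084 (adjusted p 0.0426) in the same comparison. Called genes in inhibitory neurons numbered 222 without wild-type-marrow library 2 and 237 without control library 1. Of the 6 named calls, 1 without knockout-marrow library 1, 1 without knockout-marrow library 2, 5 without wild-type-marrow library 1, 5 without wild-type-marrow library 2, 5 without control library 1 and 3 without control library 2 were lost, with an adjusted p of up to 0.395.

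The comparison of knockout-marrow mice with controls changes donor T cells and, as the control titles name the wild type, the genotype of the marrow together, and cannot separate them. In microglia and macrophages, Mndal (ENSMUSG00000090272), an interferon-inducible gene of the p200 family, had 68.3 ± 10.7 against 13.3 ± 6.52 CPM (SD, n = 2) and a log2 fold change of 2.53 ± 0.41 (adjusted p 0.0463) by edgeR. Kcnip3 (ENSMUSG00000079056), a calcium-binding protein, and Rad51b (ENSMUSG00000059060), a DNA repair gene, rose by 2.55 ± 0.37 (adjusted p 0.0278) and 1.29 ± 0.19 (adjusted p 0.0278). The 4th call was Gm12861, outside the naming rule and named after its values were seen. Cd74 had 1.93 ± 0.54 (adjusted p 0.699), H2-Ab1 2.02 ± 0.59 (adjusted p 0.621), B2m 0.54 ± 0.20 (adjusted p 0.637), Ms4a7 1.79 ± 0.42 (adjusted p 0.368) and Apoe 1.5 ± 0.65 (adjusted p 0.800). Without control library 1, Cd74, H2-Ab1 and Ms4a7 passed the test (2.58, 2.96 and 2.45). P2ry12, Csf1r, Cd274, Tgfb1 and Tmem119 had log2 fold changes of -0.28, -0.29, 0.78, -0.44 and -0.010, with adjusted p of 0.746 or more.

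No member of the interferon-gamma response list passed the test over all genes in this class, and 2 of 20 did when adjusted over the list alone. Its median was 0.45 (camera, adjusted p 1.57e-05, or adjusted p 0.284 with an estimated correlation). Without control library 2 that median was 0.20 and the list was not called (adjusted p 0.263), and without control library 1 it was 0.89. The MHC class II list had a median of 1.87, adjusted p 1.76e-08, 0.284 with an estimated correlation, with 5 of 8 risen adjusted over the list alone. The MHC class I list had a median of 0.77, adjusted p 3.42e-08, 0.284 with an estimated correlation. For the marrow-derived macrophage list the median was 1.41, adjusted p 7.39e-10, 0.284 with an estimated correlation, with 6 of 11 risen adjusted over the list alone. Cluster 19 was a larger part of the class here too than in controls, so a change of mix is not excluded for this list. In cluster 21 alone the interferon-gamma response list had a median of 0.31, the MHC class II list 1.58, and the marrow-derived list was not tested. The synapse list, genes of neurons, was lower with a median of -0.69, adjusted p 1.13e-12, 0.284 with an estimated correlation. Whether doublets with neurons that were not called carry this fall was not tested. In all, 4 genes rose and 0 fell of 9255 tested by edgeR, 608 had an unadjusted p under 0.05, and DESeq2 called 2, none of them shared. Each of the 4 calls was also lost with only the libraries of the groups compared, among nuclei with at least 1000 genes and with the replicate number as a block. Called genes in microglia and macrophages numbered 7 without wild-type-marrow library 1, 8 without wild-type-marrow library 2, 14 without knockout-marrow library 1, 2 without knockout-marrow library 2, 107 without control library 1 and 0 without control library 2. Of the 3 named calls, 1 without knockout-marrow library 1, 2 without knockout-marrow library 2 and 3 without control library 2 were lost, with an adjusted p of up to 0.635.

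In oligodendrocytes of knockout-marrow mice, Psmb8 was at least 15.4-fold higher than in controls, where it had no count. Ddx60 had 20.7 ± 2.15 against 1.13 ± 1.38 CPM (SD, n = 2), a log2 fold change of 4.87 ± 0.49 (adjusted p 0.00225) by edgeR. H2-T22 and H2-Q7 rose by 1.89 ± 0.28 (adjusted p 0.00378) and 4.05 ± 0.61 (adjusted p 0.00795), Irf1 (ENSMUSG00000018899) and Psmb9 (ENSMUSG00000096727) by 3.33 ± 0.58 (adjusted p 0.0441) and 4.84 ± 0.81 (adjusted p 0.0330), and Xaf1 and Oasl2 by 0.93 ± 0.16 (adjusted p 0.0101) and 4.51 ± 0.68 (adjusted p 0.0101). Olfr56, counted at 1 UMI in controls, rose by 4.94 ± 0.88 (adjusted p 0.0147). Slc15a2 (ENSMUSG00000022899), a peptide transporter, fell, with -3.69 ± 0.45 (adjusted p 0.00734), and Pakap and Mast4 had -0.59 ± 0.086 (adjusted p 0.00378) and -0.45 ± 0.065 (adjusted p 0.00378). C4b had 1.95 ± 0.29 (adjusted p 0.150) and passed the test without control library 1 (2.34) or 2 (1.44) and without wild-type-marrow library 2 (1.95). On the interferon-gamma response list 3 of 25 rose, or 17 adjusted over the list alone (median 3.39, 3.35 with members at 0 at their bound, adjusted p 4.4e-31, or adjusted p 0.197 with an estimated correlation). On the MHC class I list 5 of 15 rose, or 15 adjusted over the list alone (median 3.15, adjusted p 2.69e-33, or adjusted p 0.134 with an estimated correlation). Beside these lists, the mitochondrially encoded list had a median of -0.41 (adjusted p 6.55e-05, or adjusted p 0.560 with an estimated correlation). In all, 25 genes rose and 5 fell of 13175 tested, 967 had an unadjusted p under 0.05, and DESeq2 called 35. Malat1, a nuclear transcript chosen after its values were seen, had 0.40 ± 0.053 (adjusted p 0.00225) in the same comparison. Called genes in oligodendrocytes numbered 19 without knockout-marrow library 1, 18 without knockout-marrow library 2, 109 without control library 1 and 10 without control library 2. Of the 12 named calls, 7 without knockout-marrow library 1, 4 without knockout-marrow library 2, 1 without control library 1 and 9 without control library 2 were lost, with an adjusted p of up to 0.549.

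In astrocytes, Pdzph1 (ENSMUSG00000024227) rose from 70.7 ± 3.01 CPM in controls to 136 ± 13.2 with knockout marrow (SD, n = 2), a log2 fold change of 0.95 ± 0.15 (adjusted p 0.0248) by edgeR. It was the only call of 11452 genes tested, with 880 at an unadjusted p under 0.05 and 1 other gene called by DESeq2. Gfap had 0.69 ± 0.30 (adjusted p 0.646) and passed the test without knockout-marrow library 2 (1.06). The interferon-gamma response list had a median of 1.39, adjusted p 3.56e-07, 0.347 with an estimated correlation, with 6 of 20 risen adjusted over the list alone. The cholesterol synthesis list had 20 of 20 members higher and 13 risen adjusted over the list alone (median 0.51, adjusted p 5.75e-14, or adjusted p 0.308 with an estimated correlation). Beside these lists, the mitochondrially encoded list had a median of -0.58 (adjusted p 1.25e-08, or adjusted p 0.335 with an estimated correlation). Called genes in astrocytes numbered 2 without wild-type-marrow library 1, 2 without wild-type-marrow library 2, 201 without knockout-marrow library 1, 23 without knockout-marrow library 2 and 76 without control library 1. The named call was lost without control library 2, with only the libraries of the groups compared, by DESeq2 and in cluster 17 alone, with adjusted p of 0.0718 to 0.182, and over all alternatives from 4.57e-06 up.

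In excitatory neurons of knockout-marrow mice 158 genes rose and 133 fell of 18631 tested (3166 with an unadjusted p under 0.05, DESeq2 609). Fgf1 (ENSMUSG00000036585), a growth factor, had 83.9 ± 10.3 against 25.5 ± 0.360 CPM (SD, n = 2) and a log2 fold change of 1.72 ± 0.11 (adjusted p 0.000112) by edgeR. H2-D1 and B2m, the MHC class I chains, rose by 0.84 ± 0.12 (adjusted p 0.0173) and 1.16 ± 0.21 (adjusted p 0.0291), and Herc6 by 0.46 ± 0.085 (adjusted p 0.0297), or -0.12 in cluster 0 alone. Gbp7 and Tmem215 rose by 2.86 ± 0.58 (adjusted p 0.0398) and 1.43 ± 0.25 (adjusted p 0.0266). Microglial markers stood at 0.646% of their microglia and macrophage level with knockout marrow and 0.564% in controls. At these shares, that class would bring 15.3% of the rise of H2-D1, 21.8% of that of B2m and 5.61% of that of Gbp7. RNA from oligodendrocytes was not checked for these single genes. Knl1 (ENSMUSG00000027326), a kinetochore gene, fell, with -2.24 ± 0.25 (adjusted p 0.00636), as did Slc39a12 and Ptpn14, with -1.53 ± 0.30 (adjusted p 0.0363) and -1.44 ± 0.25 (adjusted p 0.0246). Slc39a12 was also a leading gene of astrocyte cluster 36, and RNA from astrocytes was not checked for its fall. The MHC class I list had a median of 0.55, adjusted p 0.00191, 0.668 with an estimated correlation. Cluster 23 held 78 and 75 in the wild-type-marrow libraries, 133 and 1 in the knockout-marrow libraries and 49 and 121 in the control libraries, and 4 genes were called in cluster 0 alone. Malat1, a nuclear transcript chosen after its values were seen, had 0.49 ± 0.076 (adjusted p 0.0193) in the same comparison. Called genes in excitatory neurons numbered 1139 without knockout-marrow library 1, 61 without knockout-marrow library 2, 4 without control library 1 and 15 without control library 2. Of the 9 named calls, 7 without knockout-marrow library 2, 1 without wild-type-marrow library 1, 2 without wild-type-marrow library 2, 8 without control library 1 and 7 without control library 2 were lost, with an adjusted p of up to 0.227.

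In inhibitory neurons 276 genes rose and 134 fell of 16092 tested (2254 with an unadjusted p under 0.05, DESeq2 354). Slc15a2 had 0.313 ± 0.119 against 8.04 ± 2.44 CPM (SD, n = 2) and a log2 fold change of -4.61 ± 0.50 (adjusted p 0.000938) by edgeR. Lcmt2 (ENSMUSG00000074890), a tRNA-modifying enzyme, rose by 1.59 ± 0.31 (adjusted p 0.0122), Prss23 (ENSMUSG00000039405), a protease, by 1.55 ± 0.27 (adjusted p 0.00673) and Ovol2 by 1.64 ± 0.41 (adjusted p 0.0466). Hsp90ab1 (ENSMUSG00000023944), a chaperone, rose by 0.37 ± 0.090 (adjusted p 0.0393). Hdc (ENSMUSG00000027360), which makes histamine, and Shox2 (ENSMUSG00000027833) fell, with -3.41 ± 0.76 (adjusted p 0.0265) and -2.65 ± 0.59 (adjusted p 0.0375). The heat shock and chaperone list had a median of 0.26, adjusted p 0.0165, 0.791 with an estimated correlation, and the mitochondrially encoded list had a median of -0.42 (adjusted p 0.00937, or adjusted p 0.868 with an estimated correlation). Cluster 20 held 249 and 63 nuclei in the knockout-marrow libraries and 584 and 472 in the control libraries. A different regional make-up is therefore not excluded for these calls. In cluster 8 alone 36 genes were called. The called genes of the class had a median change in the called direction of 0.19 there, against 0.58 in the class. Malat1, a nuclear transcript chosen after its values were seen, had 0.47 ± 0.084 (adjusted p 0.00800) in the same comparison. Called genes in inhibitory neurons numbered 621 without knockout-marrow library 1, 100 without knockout-marrow library 2 and 71 without control library 1. Of the 7 named calls, 3 without knockout-marrow library 1, 5 without knockout-marrow library 2, 1 without wild-type-marrow library 1, 1 without wild-type-marrow library 2, 6 without control library 1 and 3 without control library 2 were lost, with an adjusted p of up to 0.504.

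The direct comparison of the 2 GVHD groups asks what depends on the interferon-gamma receptor in donor marrow. In microglia and macrophages, genes induced by interferon-gamma were lower with knockout marrow. On the interferon-gamma response list, 1 of 20 members was higher and 9 fell when adjusted over the list alone (median -0.63, camera adjusted p 6.72e-12, or adjusted p 0.331 with an estimated correlation). On the MHC class II list 3 of 8 and on the MHC class I list 4 of 15 fell when adjusted over the list alone, and none over all genes. Their medians were -1.01 (adjusted p 8.94e-07, or adjusted p 0.340 with an estimated correlation) and -0.61 (adjusted p 7.57e-07, or adjusted p 0.340 with an estimated correlation). All 17 members of the resident microglia list were higher, 3 of them risen adjusted over the list alone (median 0.42, adjusted p 2.82e-09, or adjusted p 0.340 with an estimated correlation). Cluster 19 was a smaller part of the class with knockout marrow, and within cluster 21 and cluster 19 alone the median of the resident list was 0.066 (adjusted p 0.113) and 0.083 (adjusted p 0.465), so that a change of mix is not excluded. Cd74, of the MHC class II list, leads cluster 19. Values of the MHC lists within clusters are not given here, so a change of mix is not excluded for them either. The marrow-derived macrophage list had a median of -0.45, adjusted p 0.00695, 0.529 with an estimated correlation, and in cluster 19 alone a median of 0.20. Ccnd3 was higher with knockout marrow, at 847 ± 34.5 CPM against 305 ± 10.5 with wild-type marrow (SD, n = 2), a log2 fold change of 1.48 ± 0.15 (adjusted p 0.000529) by edgeR. Synapse genes were lower, with a median of -0.52, adjusted p 4.28e-09, 0.340 with an estimated correlation. A part of uncalled doublets with neurons in this fall was not tested either.

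Of the genes given whatever their result, Cd74 had -0.75 ± 0.49 (adjusted p 0.866) and 0.24 in cluster 19 alone, H2-Ab1 -1.16 ± 0.45 (adjusted p 0.729), B2m -0.31 ± 0.19 (adjusted p 0.818), Tmem119 0.73 ± 0.23 (adjusted p 0.592) and Csf1r 0.37 ± 0.15 (adjusted p 0.707) between the GVHD groups. Ms4a7, P2ry12, Apoe, Cd274 and Tgfb1 had -0.60, 0.23, -0.39, -0.20 and 0.12, all with an adjusted p of 0.813 or more, and each had the opposite sign in cluster 19 or cluster 21 taken alone. The mitochondrially encoded list was lower with knockout marrow in this class (median -1.04, adjusted p 2.77e-08, or adjusted p 0.340 with an estimated correlation), and the median mitochondrial percent of nuclei was 0.0801 and 0.0363 in the wild-type-marrow libraries, 0.00894 and 0.0355 in the knockout-marrow libraries and 0.0346 and 0.0451 in the control libraries. In all, 1 gene rose and 1 fell of 9255 tested, 621 had an unadjusted p under 0.05, and DESeq2 called 3, 1 of them shared. Called genes in microglia and macrophages numbered 0 without wild-type-marrow library 2, 11 without knockout-marrow library 1, 26 without control library 1 and 16 without control library 2. The named call was lost without wild-type-marrow library 2 (adjusted p 0.0703).

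In oligodendrocytes, Ccnd3 was higher with knockout marrow, at 163 ± 15.0 CPM against 84.5 ± 10.6 (SD, n = 2), a log2 fold change of 0.95 ± 0.11 (adjusted p 0.000827) by edgeR. Klk6 (ENSMUSG00000050063), a protease of myelin-forming cells, and Arhgef37 (ENSMUSG00000045094) rose by 1.39 ± 0.25 (adjusted p 0.0444) and 1.09 ± 0.20 (adjusted p 0.0444). Sema6a (ENSMUSG00000019647), a guidance molecule, Alk (ENSMUSG00000055471), a receptor kinase, and Slc15a2 fell, with -0.59 ± 0.078 (adjusted p 0.00240), -1.24 ± 0.19 (adjusted p 0.0153) and -3.42 ± 0.48 (adjusted p 0.0336). C4b had -0.22 ± 0.24 (adjusted p 0.867), or 0.046 without wild-type-marrow library 2 and 0.098 in cluster 24 alone. All 25 measured members of the interferon-gamma response list were lower, 2 fallen adjusted over the list alone (median -0.78, adjusted p 3.77e-10, or adjusted p 0.488 with an estimated correlation). On the glucocorticoid target list 5 of 12 rose adjusted over the list alone and none over all genes (median 0.83, adjusted p 2.42e-12, or adjusted p 0.488 with an estimated correlation). Beside these lists, the mitochondrially encoded list had a median of -1.08 (adjusted p 1.54e-12, or adjusted p 0.488 with an estimated correlation). In all, 11 genes rose and 6 fell of 13175 tested, 1112 had an unadjusted p under 0.05, and DESeq2 called 19. Malat1, a nuclear transcript chosen after its values were seen, had 0.31 ± 0.053 (adjusted p 0.0258) in the same comparison. Called genes in oligodendrocytes numbered 26 without wild-type-marrow library 1, 6 without wild-type-marrow library 2, 35 without knockout-marrow library 1, 4 without knockout-marrow library 2, 39 without control library 1 and 37 without control library 2. Of the 6 named calls, 2 without knockout-marrow library 1, 5 without knockout-marrow library 2, 3 without wild-type-marrow library 1 and 3 without wild-type-marrow library 2 were lost, with an adjusted p of up to 0.550.

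In astrocytes, Zbtb16 (ENSMUSG00000066687), a glucocorticoid-induced transcription factor, had 133 ± 1.84 CPM with knockout marrow against 46.7 ± 1.93 with wild-type marrow (SD, n = 2), a log2 fold change of 1.5 ± 0.23 (adjusted p 0.0239) by edgeR. Etnppl (ENSMUSG00000019232), an enzyme of lipid breakdown, and Hif3a (ENSMUSG00000004328), a hypoxia-inducible factor, rose by 1.32 ± 0.20 (adjusted p 0.00936) and 1.27 ± 0.16 (adjusted p 0.00130). Mertk (ENSMUSG00000014361), a phagocytic receptor, rose by 0.58 ± 0.11 (adjusted p 0.0325) and Hsp90ab1 by 0.83 ± 0.15 (adjusted p 0.0325). Gfap had 0.26 ± 0.31 (adjusted p 0.935), or -0.20 without knockout-marrow library 1. The interferon-gamma response list had 3 of 20 members higher and a median of -0.75, adjusted p 7.52e-10, 0.325 with an estimated correlation. The heat shock and chaperone list had 1 of 8 risen, or 4 adjusted over the list alone (median 0.64, adjusted p 3.14e-06, or adjusted p 0.325 with an estimated correlation). In the same nuclei the mitochondrially encoded list had a median of -0.91 (adjusted p 2.22e-15, or adjusted p 0.325 with an estimated correlation), and Gapdh, chosen after its values were seen, had 0.89 ± 0.16 (adjusted p 0.0325). In all, 9 genes rose and 0 fell of 11452 tested, 787 had an unadjusted p under 0.05, and DESeq2 called 4. Called genes in astrocytes numbered 3 without wild-type-marrow library 1, 2 without wild-type-marrow library 2, 50 without knockout-marrow library 1, 43 without knockout-marrow library 2, 15 without control library 1 and 14 without control library 2. Of the 5 named calls, 5 without wild-type-marrow library 1 and 4 without wild-type-marrow library 2 were lost, with an adjusted p of up to 0.754.

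In excitatory neurons, Hspa5 had 49.5 ± 0.0786 CPM with knockout marrow against 26.6 ± 2.64 with wild-type marrow (SD, n = 2), a log2 fold change of 0.90 ± 0.085 (adjusted p 0.00576) by edgeR. Hsp90ab1 rose by 0.44 ± 0.062 (adjusted p 0.0366), Trib2 (ENSMUSG00000020601), a pseudokinase, by 0.95 ± 0.12 (adjusted p 0.0276) and Lcmt2 by 1.61 ± 0.22 (adjusted p 0.0366), and Knl1 fell, with -2.45 ± 0.24 (adjusted p 0.00576). The heat shock and chaperone list had 2 of 11 risen, or 4 adjusted over the list alone (median 0.29, adjusted p 1.53e-05, or adjusted p 0.499 with an estimated correlation). In the same nuclei the mitochondrially encoded list had a median of -1.0 (adjusted p 5.96e-08, or adjusted p 0.792 with an estimated correlation), and Gapdh, chosen after its values were seen, had 0.55 ± 0.077 (adjusted p 0.0366). In all, 10 genes rose and 1 fell of 18631 tested, 1616 had an unadjusted p under 0.05, and DESeq2 called 54. Called genes in excitatory neurons numbered 47 without wild-type-marrow library 1, 1 without wild-type-marrow library 2, 53 without knockout-marrow library 1 and 41 without knockout-marrow library 2. Of the 5 named calls, 1 without knockout-marrow library 1, 1 without knockout-marrow library 2, 2 without wild-type-marrow library 1, 5 without wild-type-marrow library 2, 2 without control library 1 and 2 without control library 2 were lost, with an adjusted p of up to 0.434.

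In inhibitory neurons, Hspa5 had 74.1 ± 1.89 against 41.2 ± 1.53 CPM (SD, n = 2), a log2 fold change of 0.85 ± 0.10 (adjusted p 0.00312) by edgeR. Hspa8 (ENSMUSG00000015656), a heat shock cognate chaperone, and Ubb (ENSMUSG00000019505), a ubiquitin gene, rose by 0.74 ± 0.088 (adjusted p 0.00312) and 0.66 ± 0.10 (adjusted p 0.0437), and Slc15a2 fell, with -4.13 ± 0.54 (adjusted p 0.0172). The heat shock and chaperone list had 2 of 9 risen, or 5 adjusted over the list alone (median 0.26, adjusted p 1.59e-07, or adjusted p 0.666 with an estimated correlation). In the same nuclei the mitochondrially encoded list had a median of -0.91 (adjusted p 8.68e-11, or adjusted p 0.666 with an estimated correlation), and Gapdh, chosen after its values were seen, had 0.62 ± 0.10 (adjusted p 0.0630). In all, 3 genes rose and 1 fell of 16092 tested, 1005 had an unadjusted p under 0.05, and DESeq2 called 4. Called genes in inhibitory neurons numbered 10 without wild-type-marrow library 2, 11 without knockout-marrow library 1 and 15 without knockout-marrow library 2. Of the 4 named calls, 1 without knockout-marrow library 1, 2 without knockout-marrow library 2, 1 without wild-type-marrow library 1 and 1 without wild-type-marrow library 2 were lost, with an adjusted p of up to 0.154.

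**Figure D3:**
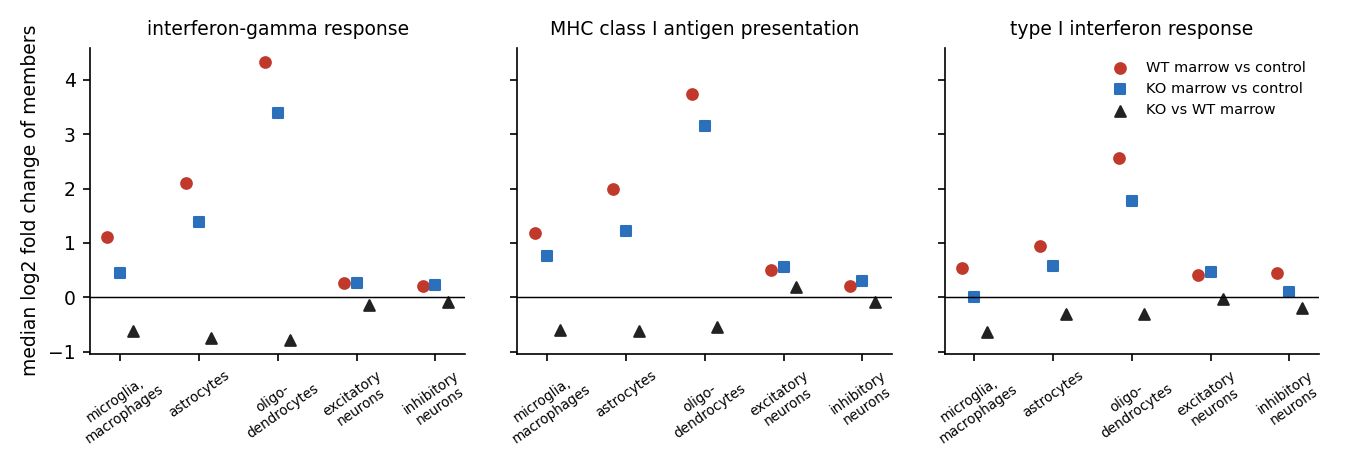
Median log2 fold change of the measured members of the interferon-gamma response, MHC class I and type I interferon lists in 5 cell classes. Circles are wild-type marrow against control, squares knockout marrow against control and triangles knockout against wild-type marrow.

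Endothelial nuclei numbered 12 and 17 in the wild-type-marrow libraries, 15 and 15 in the knockout-marrow libraries and 3 and 10 in the control libraries, fewer than 20 in each library, and their expression was not tested. Over the 5 classes and 3 comparisons, no list called by camera with its preset correlation was called with an estimated correlation, where the smallest adjusted p was 0.105, or by fry, where it was 0.0645. The lists overlap: 12 of 35 genes of the interferon-gamma response list and 10 of 16 of the MHC class I list stand in another list. H2-Ea and H2-Ea-ps were not in the list of measured genes. Genes of the MHC class I, guanylate-binding protein and Ly49 families have near-identical copies, and the recipients carry alleles from 2 strains counted against 1 reference, so single members of these families are uncertain.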

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

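All tests of explanations below were chosen after the results were seen, as were the single clusters. In microglia and macrophages, the interferon-gamma response list was lower with knockout than with wild-type marrow, with a median log2 fold change of -0.63. A different mix of the 2 clusters is argued against by cluster 19 and cluster 21 taken alone, with medians of -0.79 and -0.52. Of the 20 members, 13 were tested in cluster 19 and 15 in cluster 21, and 12 and 14 of these were lower. A change of mix inside a cluster, such as cluster 19 with 33.8% called doublets, was not tested. RNA from other cells is argued against by excitatory neurons, where the 20 members summed to a fall of -0.578 CPM, a slight rise. Times the ratio of median UMI counts, 5.06, this is -0.316% of their fall of 925 CPM in microglia and macrophages. The list was also lower between these groups, by camera with its preset correlation only, in classes that marrow does not form, with medians of -0.78 in oligodendrocytes and -0.75 in astrocytes, though 0.082 in precursors, and T and NK cells made up 0.0997% against 0.273% of nuclei (exact permutation p = 0.333, n = 2 each). The genotype of the marrow and a difference across the whole brain, as in T cells, both stay open, untested against each other.

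Interferon-induced and MHC class I genes were higher in oligodendrocytes with wild-type marrow and T cells than in controls. RNA from other cells would give a like rise in every class, and the rise of the 20 called members in excitatory neurons, 17.3 CPM, times the ratio of median UMI counts, is 24.8% of their rise of 306 CPM in oligodendrocytes. Microglia or macrophages among the oligodendrocytes, from 18 marker genes, would bring 1.72% of it. In cluster 24 alone the 11 members tested had a median of 2.31 against 2.57 in the class, which argues against a different make-up of its clusters. An effect of donor T cells on oligodendrocytes may remain as a hypothesis, found and tested on the same data.

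Many genes were called in neurons with wild-type marrow and T cells against controls. For the 590 called genes tested in inhibitory cluster 8 alone, the median change in the called direction was 0.20 against 0.57 in the class, so that a different regional make-up of the libraries is a candidate explanation. For excitatory neurons the median in cluster 0 alone was 0.42 against 0.58 in the class over 241 genes, 219 of them in the called direction. The part that stays within cluster 0 is not made by a mix of clusters. How much regional make-up adds to the rest was not tested, nor was a change of mix inside cluster 0. With knockout marrow against controls the medians were 0.19 against 0.58 and 0.30 against 0.55. An effect of donor T cells on neurons stays open, untested.

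Single genes differed between the GVHD groups in a direct test by edgeR, with knockout marrow against wild-type marrow. Ccnd3 had 1.48 in microglia and macrophages and 0.95 in oligodendrocytes. In astrocytes, Zbtb16 had 1.5, Etnppl 1.32 and Hif3a 1.27. In oligodendrocytes, Slc15a2 had -3.42, Alk -1.24 and Sema6a -0.59. In excitatory neurons, Lcmt2 had 1.61, Trib2 0.95, Hspa5 0.90 and Knl1 -2.45. In inhibitory neurons, Hspa5 had 0.85, Hspa8 0.74, Ubb 0.66 and Slc15a2 -4.13. A difference of genetic background between the mice of the groups was not tested for these genes.

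T and NK cells lie outside the comparisons above. They made up 0.273 ± 0.0314% of nuclei with wild-type marrow and 0.0997 ± 0.0479% with knockout marrow, against 0.0276 ± 0.00252% in controls (SD, n = 2; two-sided exact permutation p = 0.333 for each pair of groups, the smallest these tests allow), and numbered 21 and 32 in the wild-type-marrow libraries, 16 and 7 in the knockout-marrow libraries and 2 and 3 in the control libraries. In oligodendrocyte precursors, the interferon-gamma response list had a median of 0.82 with wild-type marrow and 0.87 with knockout marrow against controls, and the MHC class I list 1.68 and 1.33. By camera their adjusted p were 0.00104 and 0.0369, and 1.81e-09 and 0.000119. With an estimated correlation no list was called in precursors, with adjusted p of 0.148 and 0.275 or more, nor by fry. These lists were picked from those tested in precursors after their values were seen.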

How the results depend on the processing

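Single clusters taken alone were chosen after seeing the data, the other settings were planned. Counts of called genes are given in the order wild-type marrow against control, knockout marrow against control and knockout against wild-type marrow. As tested above they were 67, 4 and 2 in microglia and macrophages, 70, 1 and 9 in astrocytes, 109, 30 and 17 in oligodendrocytes, 253, 291 and 11 in excitatory neurons and 682, 410 and 4 in inhibitory neurons. Without a filter on low counts they were 249, 123 and 98 in microglia and macrophages, 244, 148 and 70 in astrocytes, 294, 157 and 160 in oligodendrocytes, 846, 941 and 122 in excitatory neurons and 1381, 1043 and 110 in inhibitory neurons. By the DESeq2 test they were 26, 2 and 3 in microglia and macrophages, 39, 1 and 4 in astrocytes, 69, 35 and 19 in oligodendrocytes, 571, 609 and 54 in excitatory neurons and 531, 354 and 4 in inhibitory neurons. With only the libraries of the groups compared they were 35, 0 and 4 in microglia and macrophages, 163, 0 and 7 in astrocytes, 67, 39 and 24 in oligodendrocytes, 750, 129 and 5 in excitatory neurons and 849, 407 and 4 in inhibitory neurons. With doublets kept they were 231, 14 and 9 in microglia and macrophages, 59, 1 and 5 in astrocytes, 109, 32 and 18 in oligodendrocytes, 223, 267 and 11 in excitatory neurons and 642, 381 and 2 in inhibitory neurons. Among nuclei with at least 1000 genes they were 42, 0 and 2 in microglia and macrophages, 77, 1 and 9 in astrocytes, 87, 31 and 12 in oligodendrocytes, 263, 290 and 11 in excitatory neurons and 690, 419 and 4 in inhibitory neurons. At Leiden resolution 2 they were 276, 45 and 24 in microglia and macrophages, 70, 1 and 9 in astrocytes, 59, 15 and 17 in oligodendrocytes, 465, 403 and 38 in excitatory neurons and 771, 412 and 5 in inhibitory neurons. In cluster 21 alone they were 24, 23 and 9 in microglia and macrophages, and in the largest shared cluster 64, 4 and 13 in astrocytes, 61, 19 and 22 in oligodendrocytes, 166, 4 and 18 in excitatory neurons and 77, 36 and 24 in inhibitory neurons. At resolution 2 the classes themselves held other nuclei. A cluster of 588 oligodendrocyte candidates, led by Gm4951, Iigp1 and Irgm2, went unnamed. A doublet cluster of 276 nuclei left the microglia and macrophage class. Clusters of 1505 and 4214 nuclei, which share leading genes with unnamed cluster 1 of resolution 1, were named excitatory neurons. How much of the shifts this or another cause made was not tested. With RLE size factors each count stayed within 1.5 times.

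Leaving out each library in turn gave, in the same order, 15 to 105, 0 to 107 and 0 to 26 in microglia and macrophages, 5 to 229, 1 to 201 and 2 to 50 in astrocytes, 32 to 164, 10 to 109 and 4 to 39 in oligodendrocytes, 5 to 784, 4 to 1139 and 1 to 53 in excitatory neurons and 222 to 887, 71 to 621 and 4 to 15 in inhibitory neurons, a lone library being assumed to vary like the other groups. The difference in the share of microglia and macrophages ran over 0.637 to 1.64, -0.558 to 0.761 and -1.70 to -0.377 points, with -0.131 without control library 1, and was -0.106 for knockout marrow against control among nuclei with at least 1000 genes. Over non-neuronal nuclei the differences kept their direction, with 5.50, 0.889 and -4.61 points. The median of the interferon-gamma response list in this class ran over 0.92 to 1.5, 0.20 to 0.89 and -0.93 to -0.65. These medians, 1.11, 0.45 and -0.63, were not called with an estimated correlation or by fry.

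Of 2284 values of 156 named results under the alternatives, 1778 kept direction and side of the threshold, 434 were no longer called, 47 became called and 25 changed sign. Those that changed sign follow. Ifngr2, wild-type marrow against control, had 0.0088 with only the groups compared, 0.22 without wild-type-marrow library 2 and 0.021 at Leiden resolution 2 (against -0.27 without wild-type-marrow library 1). Tmem119, knockout marrow against control, had 0.041 without knockout-marrow library 1, 0.0090 without control library 1, 0.039 with at least 1000 genes and 0.082 in cluster 21 alone (against -0.045 without knockout-marrow library 2). Cd74, knockout against wild-type marrow, had 0.24 in cluster 19 alone. Apoe, knockout against wild-type marrow, had 0.28 without wild-type-marrow library 1, 0.33 in cluster 19 alone and 0.48 in cluster 21 alone (against -0.84 without wild-type-marrow library 2). P2ry12, knockout against wild-type marrow, had -0.081 in cluster 19 alone and -0.079 in cluster 21 alone. Ms4a7, knockout against wild-type marrow, had 0.20 in cluster 19 alone. Cd274, knockout against wild-type marrow, had 0.030 without wild-type-marrow library 1, 0.077 without knockout-marrow library 2, 0.032 with at least 1000 genes and 0.24 in cluster 19 alone (against -0.44 without knockout-marrow library 1). Tgfb1, knockout against wild-type marrow, had -0.020 without knockout-marrow library 2 and -0.12 in cluster 21 alone (against 0.25 without knockout-marrow library 1). Gfap, knockout against wild-type marrow, had -0.20 without knockout-marrow library 1 (against 0.64 without knockout-marrow library 2). C4b, knockout against wild-type marrow, had 0.046 without wild-type-marrow library 2 and 0.098 in the largest shared cluster (against -0.41 without wild-type-marrow library 1). Herc6, wild-type marrow against control, had -0.12 in the largest shared cluster. Herc6, knockout marrow against control, had -0.12 in the largest shared cluster. The marrow-derived macrophage list, knockout against wild-type marrow, had 0.20 in cluster 19 alone. Of 340 values of the other lists 196 kept their call and 143 lost it, 112 of these with an estimated correlation.

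With the replicate number as a block, counts of called genes were 32, 0 and 1 in microglia and macrophages, 63, 2 and 3 in astrocytes, 80, 24 and 8 in oligodendrocytes, 328, 291 and 10 in excitatory neurons and 1015, 732 and 3 in inhibitory neurons. Across 15 pairs of groups in a class, the differences between replicates correlated across genes at -0.22 to 0.13, so the numbers were not taken to pair the libraries.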

Other observations

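Striatal projection neurons made up 2.63 and 9.30 in the wild-type-marrow libraries, 2.62 and 7.89 in the knockout-marrow libraries and 2.04 and 3.59 in the control libraries, in percent of nuclei. Cluster 16, left without a name, held 30 and 97 in the wild-type-marrow libraries, 1002 and 54 in the knockout-marrow libraries and 43 and 80 in the control libraries. The mitochondrially encoded list had medians of -1.04, -0.91, -1.08, -1.0 and -0.91 for knockout against wild-type marrow in microglia and macrophages, astrocytes, oligodendrocytes, excitatory and inhibitory neurons. In striatal projection neurons edgeR called 0 genes in each comparison, with 518, 444 and 220 at an unadjusted p under 0.05 and 0 by DESeq2. In oligodendrocyte precursors edgeR called 7, 50 and 3 and DESeq2 0, 11 and 2, with 0, 10 and 1 shared. Malat1 had 0.37 ± 0.074 (adjusted p 0.0104) there by edgeR with knockout marrow against controls.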
